A study of Mus musculus with 15 samples.

How the data were processed

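RNA from pancreatic islets of 11 week old mice was sequenced as paired-end libraries made with a stranded, poly(A)-selecting kit, per the labels' protocols. The 15 samples form 5 groups of 3. Ep300_control islets carried floxed Ep300 alleles without Cre, and p300_KO islets carried the same alleles with a Cre recombinase driven by the Neurog3 promoter, which is active in the precursors of all islet endocrine cells. Crebbp_control and CBP_KO are the matching pair for floxed Crebbp. Triallelic islets carried Neurog3-Cre, both floxed Ep300 alleles and 1 floxed Crebbp allele. Every knockout sample carried Cre and no control sample did, so Cre and the deletions cannot be separated. The series description mentions 2 sequencing batches for the p300 samples without assigning them, so no batch term was fitted. Replicates were numbered in accession order. The labels do not say that the samples of a group came from separate animals, so all p-values measure only the spread between these samples.

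The authors deposited 1 table of whole-number read counts per gene for the series. Per the submitters' processing notes, TopHat2, DESeq2 and the mouse genome build mm10 were used. Their versions, the read counter, the annotation and the handling of strand and of multiply mapped reads are not given in the sources used here. The count table has 27179 genes under numeric gene identifiers. Of these, 25275 were named from a RefSeq gene table of assembly GRCm38.p6, 49 from the authors' gene lists, and 1855 stayed without a name. The table has 1 count column that matches no sample label, and it was not used. Its name differs by 1 digit from that of the p300_KO sample without a column, so a typing error is possible, but no label or file settles it. The third p300_KO sample was therefore not analysed here, which left 14 libraries with 2 in the p300_KO group.

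The authors also deposited gene lists for the 3 knockouts, which hold only genes with an adjusted p-value under 0.05. Per the file headers these lists give a log2 fold change, a p-value and an adjusted p-value per gene. Per the file headers they also give a signal column, the mean of normalized counts over samples. Further tables by the authors list enriched gene sets, with a ratio of observed to expected genes per the file headers. The tool and the background behind those enrichment tables are not given in the sources used here. Values from these tables were read as deposited and were not recomputed.

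The quasi-likelihood test of edgeR had been planned but was not used, because the columns of the count table could not be read by an automatic check of their unit. The counts were tested with limma-voom instead, which works on the logarithm of counts scaled by library size (log2 CPM) with precision weights. Genes entered the test with at least 10 counts at the median library size in at least 2 libraries and at least 15 counts in all, which left 16126 genes. Library sizes were scaled with trimmed means of M-values, voom added 0.5 counts before taking logarithms, and 1 linear model with a mean for each of the 5 groups was fitted to all 14 libraries, with 9 residual degrees of freedom. Contrasts were tested with limma's robust moderated test (two-sided), adjusted by the Benjamini-Hochberg method over all genes tested, and called at an adjusted p under 0.05. The software was R 4.3.3 with limma 3.58.1 and statmod 1.5.0. Fitted fold changes of genes near 0 counts depend on the added count.

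The 6 contrasts were p300_KO against Ep300_control, CBP_KO against Crebbp_control, Triallelic against the equally weighted mean of both control groups, Ep300_control against Crebbp_control, the CBP change minus the p300 change, and Triallelic against p300_KO. Triallelic islets have no control group of their own genotype. Levels in the text are CPM scaled in the same way, as mean ± SD over the libraries of a group. The deleted genes were compared with exact permutation tests (two-sided) on CPM.

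A total of 23 gene lists were written, as were the groups, contrasts, alternative settings and naming rule, before the data were examined. The lists hold 346 distinct genes, some of them in more than 1 list. They cover beta cell identity and function, alpha cell markers, delta, PP and epsilon cell markers, acinar, ductal, endothelial, immune, and Schwann and glial cell markers, mesenchymal, stellate and pericyte markers, HNF1A and its islet targets, cell proliferation, G1 cyclins and CDK inhibitors, cAMP and CREB target and immediate early genes, the unfolded protein and integrated stress response, genes repressed in normal beta cells, dedifferentiation and progenitor markers, granule and exocytosis genes, histone acetyltransferases and deacetylases other than p300 and CBP, oxidative phosphorylation, cholesterol synthesis, hypoxia, interferon response, and sex-linked genes. Each list was tested with limma's camera (two-sided, preset correlation between genes of 0.01, Benjamini-Hochberg over the 23 lists of a contrast). Camera with a correlation estimated from the data and the rotation test fry were run beside it. Fry asks whether the genes of a list move, on balance, in 1 direction, without comparing them with other genes.

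The text names, for each knockout contrast, the deleted genes, 5 hormone genes, up to 3 members of each list with the smallest adjusted p among those called or otherwise the most abundant member, and the 5 genes with the largest rise and fall among called genes with a mean log2 CPM of at least 1 and non-overlapping libraries, leaving out predicted genes. For the other contrasts it names 3 and 3. Genes named outside this rule are said to have been chosen after their values were seen. Because p300_KO gave no called gene in the model of all libraries, the rule was also applied to the fit of these 2 groups alone, which had been set in advance as another setting.

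Alternatives covered another scaling, the count filter, the variance estimate, the samples in the fit, the control group and leaving out each library. Weights per library, limma-trend and leaving out a pair of doubtful libraries were added after seeing the data. The whole procedure was tested on simulated counts drawn from the means and sizes of the real libraries, with 200 of 16126 genes changed. For the p300 contrast it recovered 55.2% of genes changed 2-fold and 93.9% of those changed 8-fold, for the CBP contrast 70.1% and 95.5%, and for the Triallelic contrast 80.6% and 98.5%. Of the calls in those simulations, 3.21%, 4.55% and 7.58% were false. For the CBP change minus the p300 change it recovered 19.4% and 90.9%, with 6.57% of calls false. Each simulated gene had the median spread of genes of similar level, and no simulated library was displaced from its group. The real contrasts, those for p300 and CBP included, may therefore miss more genes than these shares say, also among large changes. Libraries held 13037284 to 46586260 counts, so that even genes of a few CPM rest on many reads, and the number of samples limits the precision more than depth does. The chi-square of counts between replicates was 8.82 to 101 per degree of freedom, so no pair of libraries was a repeat within sampling noise. Ins1 and Ins2, the trypsin genes and the immunoglobulin genes have near-identical relatives, and the split of reads among them is uncertain, as it is for overlapping genes.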

Results

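Gene expression was measured by RNA sequencing in islets of mice that lacked the histone acetyltransferase p300 (gene Ep300), its paralog CBP (gene Crebbp), or p300 together with 1 copy of CBP, in the endocrine lineage. The design asks what each coactivator contributes to islet gene expression and what is lost when 3 of the 4 alleles are deleted. Ep300_control libraries (n = 3) held 14886497 to 19528276 counts and p300_KO libraries (n = 2) 19218585 and 21126158. Crebbp_control (n = 3) held 13443678 to 16839685 and CBP_KO (n = 3) 13037284 to 15728042. The Triallelic libraries (n = 3) held 46586260, 14044673 and 13849749 counts.

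The first principal component, with 39.1% of the variance, separated the 5 libraries of the Ep300 line, control and knockout alike (-91.4 to -75.0), from all others (33.8 to 57.2). The second, with 31.3%, set the Triallelic libraries apart (-128 to -55.8). Correlations of log2 CPM within groups were 0.985 to 0.988 in Ep300_control, 0.982 in p300_KO, 0.969 to 0.983 in Crebbp_control, 0.961 to 0.984 in CBP_KO and 0.930 to 0.960 in Triallelic. The library labelled Triallelic 1 stood out as male. Xist, expressed from the inactive X chromosome, was at 0.470 CPM in it against 2825 and 2325 CPM in the other Triallelic libraries. The Y-linked gene Ddx3y was at 122.6 CPM in it and 0 CPM in the others.

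**Figure D1:**
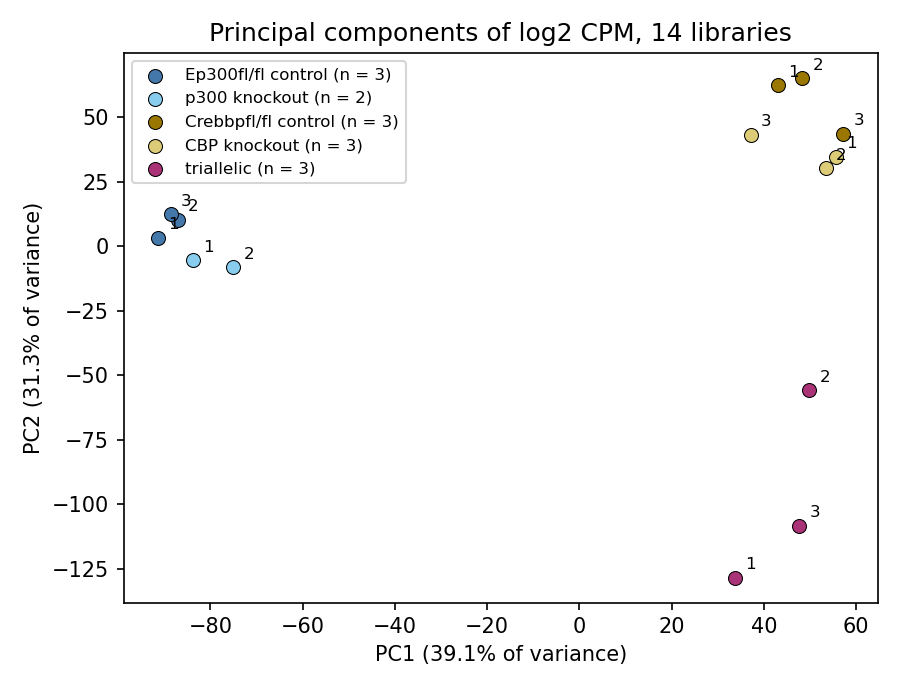
Each point is 1 of the 14 libraries, placed by its scores on the first (39.1% of variance) and second (31.3%) principal components of log2 CPM and coloured by group. Libraries of the Ep300 line sit at negative scores on the first axis, and the 3 Triallelic libraries at negative scores on the second.

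The deleted genes had lower means in their own knockouts, and neither difference passed a test. Ep300 (chromosome 15, 81586209 to 81652077, GRCm38.p6) was at 69.1 ± 27.7 CPM in p300_KO (SD, n = 2) and 98.4 ± 21.5 CPM in Ep300_control (SD, n = 3), or 70.2% of control (exact permutation test, two-sided, p = 0.4, and 0.6 after adjustment over 6 such tests). The p300_KO libraries held 49.5 and 88.7 CPM of Ep300 and the control libraries 81.9 to 122.7 CPM, so p300_KO 2 lay within the range of the controls. This difference of -29.3 CPM was larger than the SD of either group, with a log2 difference of -0.55 (SE 0.27, limma adjusted p = 0.936). Crebbp (chromosome 16, 4081334 to 4213957) was at 72.2 ± 14.02 CPM in CBP_KO and 85.2 ± 5.34 CPM in Crebbp_control (SD, n = 3 each), or 84.8% (exact permutation p = 0.3, and 0.6 after adjustment). The CBP_KO libraries held 64.8, 63.5 and 88.4 CPM of Crebbp, the control libraries 79.7, 90.4 and 85.4 CPM, so the library labelled CBP_KO 3 lay within the range of the controls. In Triallelic islets Ep300 was at 94.3 ± 12.5 CPM against 129 ± 47.4 CPM in the 6 control libraries (73.0%, exact permutation p = 0.262), and Crebbp at 94.0 ± 23.5 CPM against 64.7 ± 23.2 CPM (145%, exact permutation p = 0.131). Those 6 libraries pool lines that differ in both genes. Set against the control group of the same floxed gene, Triallelic Ep300 stood beside 98.4 CPM in Ep300_control and Triallelic Crebbp beside 85.2 CPM in Crebbp_control. These percentages therefore depend on the line used as control. Ep300 was at 80.5 to 104.7 CPM in the Triallelic libraries, near Ep300_control but below every Crebbp_control library (124.8 to 214.7 CPM). Triallelic islets have no control group of their own genotype, so whether Ep300 fell is not settled here. The paralog did not differ detectably in either single knockout: Crebbp was at 63.2 ± 32.3 CPM in p300_KO against 44.2 ± 7.81 CPM (exact permutation p = 0.6), and Ep300 at 169 ± 14.1 CPM in CBP_KO against 160 ± 47.9 CPM (exact permutation p = 0.9). With 2 against 3 and with 3 against 3 libraries the smallest possible p is 0.1, so these exact tests could not pass. Whole-gene counts include exons outside the deleted part, which the labels do not specify, and RNA of islet cells without Cre, so they check the genotypes only weakly.

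The control groups of the lines, neither of which carried Cre, already differed widely. Among the genes with the largest differences, Dcn, which encodes the matrix proteoglycan decorin, was at 459 ± 1.82 CPM in Ep300_control and 1.70 ± 0.660 CPM in Crebbp_control (SD, n = 3 each; log2 difference 8.17). Smoc2, a secreted calcium-binding matrix protein, was at 83.9 ± 3.03 and 0.283 ± 0.322 CPM (8.51), and Abca8a at 34.8 ± 2.49 and 0.128 ± 0.0486 CPM (7.76). In the opposite direction, Nrtn, which encodes the neurotrophic factor neurturin, was at 0.297 ± 0.132 CPM in Ep300_control and 8.54 ± 1.504 CPM in Crebbp_control (-4.81). Tmsb15b2 (-3.85) and Atg4a (-3.64) were also lower in the Ep300 line. Of the gene lists, 8 of 12 mesenchymal, stellate and pericyte markers, 11 of 15 immune cell markers and 13 of 18 acinar cell markers were higher in Ep300_control, and 0 were lower (9, 11 and 16 higher adjusted over the list alone). Each of these lists passed (camera adjusted p = 8.17e-07, and camera adjusted p = 0.505 with an estimated correlation). Of the genes repressed in normal beta cells, 8 of 15 were higher (9 adjusted over the list alone; camera adjusted p = 0.00261, and camera adjusted p = 0.505 with an estimated correlation). Of the beta cell identity genes, 1 was higher and 7 of 26 lower (1 and 8 adjusted over the list alone; camera adjusted p = 0.00467, and camera adjusted p = 0.505 with an estimated correlation). The transcription factor genes Mafa (-3.39) and Nkx6-1 (-1.96), named after their values were seen, were among the lower ones, and Trpm5 (1.35), named in the same way, was the higher one. Of the granule genes 4 of 20 were lower (5 adjusted over the list alone; camera adjusted p = 0.00358, and camera adjusted p = 0.494 with an estimated correlation). The cAMP and immediate early list had 6 higher members and 1 lower of 20 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0386, and camera adjusted p = 0.505 with an estimated correlation). Oxidative phosphorylation had 4 higher and 1 lower of 22 (5 and 1 adjusted over the list alone; camera adjusted p = 0.0396, and camera adjusted p = 0.787 with an estimated correlation).

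In all, limma called 1507 genes higher and 1334 lower in Ep300_control than in Crebbp_control, of 16126 tested. The libraries of the groups did not overlap for 46.5% of genes, against 10% by chance. The size of the count depended on single libraries: it was 1307, 1663 and 1698 without Ep300_control 1, 2 and 3, and 1473 and 1623 without Crebbp_control 2 and 3. Low counts of Y-linked genes accompanied this difference. Ddx3y stood at 2.14 to 2.91 CPM in all 5 libraries of the Ep300 line, which had Xist at 1132 to 1593 CPM, and at most 0.131 CPM in the 6 libraries of the Crebbp line.

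Loss of p300 gave no called gene in the model of all 14 libraries, in which the hormone genes of the islet had these values. Gcg, which encodes glucagon (chromosome 2, 62474530 to 62483653), was at 26875 ± 6540 CPM in p300_KO (SD, n = 2) and 50617 ± 1865 CPM in Ep300_control (SD, n = 3; log2 difference -0.93, SE 0.36, limma adjusted p = 0.936). Sst, which encodes somatostatin, was at 3174 ± 161 against 1650 ± 46.6 CPM (0.94, SE 0.26, limma adjusted p = 0.721). Ppy, which encodes pancreatic polypeptide, was at 1282 ± 214 against 2378 ± 303 CPM (-0.89, SE 0.86, limma adjusted p = 0.947). The insulin genes Ins1 (0.21, SE 0.46) and Ins2 (-0.19, SE 0.42) lay within the spread between samples. Limma called 0 genes higher and 0 lower, with 803 genes at an unadjusted p under 0.05 where 806 are given by chance, and limma-trend also called 0. The libraries did not overlap for 30.2% of genes, against 20% by chance.

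When only the libraries of these groups were fitted, a choice made in advance, limma called 32 genes higher and 90 lower in p300_KO. Among the largest falls were Msln, which encodes the surface protein mesothelin (-4.55, SE 0.27, limma adjusted p = 0.00118; 119 ± 18.6 CPM in Ep300_control and 5.33 ± 2.37 CPM in p300_KO) and the cadherin gene Cdh7 (-3.22; 17.1 ± 3.39 and 1.89 ± 0.763 CPM). They also included the melanophilin gene Mlph (-3.15), the water channel gene Aqp4 (-3.11, SE 0.27, limma adjusted p = 0.00338; 37.1 ± 9.15 and 4.20 ± 0.0875 CPM) and the adenosine receptor gene Adora3 (-2.77; 64.2 ± 2.24 and 9.68 ± 3.01 CPM). Dpp4, which encodes the incretin-degrading peptidase and was on the alpha cell list, also fell (-2.03; 210 ± 10.1 and 52.9 ± 16.4 CPM), as did Serpina7, which encodes thyroxine-binding globulin (-1.90). Ghrl, which encodes the epsilon cell hormone ghrelin, rose by 3.18 (limma adjusted p = 0.0418; 4.14 ± 3.54 and 31.2 ± 11.2 CPM). So did Shisa7 (2.80), the neuronal filament gene Prph (2.02), the complexin gene Cplx1, the neuroligin gene Nlgn3 (1.85), the tight junction gene Cldn3 (1.44) and Mafa, a transcription factor of mature beta cells (1.28, limma adjusted p = 0.0241; 17.1 ± 3.17 and 41.4 ± 4.21 CPM). The model of all libraries gave nearly the same log2 differences (Msln -4.55, Aqp4 -3.10) with larger errors (SE 1.54 and 1.53) and called none. It called 80 genes (17 higher, 63 lower) without the libraries labelled Crebbp_control 3 and CBP_KO 3 and 7 with weights per library, both chosen after seeing the data.

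As groups, exocrine markers and the combined list of delta, PP and epsilon cell markers passed camera upward in p300_KO, and 2 metabolic lists passed downward. Within the combined list Sst was positive (0.94) and Ppy, the PP cell hormone gene, negative (-0.89), so its members did not move alike. No list kept its call with an estimated correlation, and limma called 0 members of any list in the model of all libraries. All 18 acinar markers had a positive log2 difference, with a median of 0.89 (camera adjusted p = 2.11e-06, and camera adjusted p = 0.584 with an estimated correlation; 0 called adjusted over the list alone). Their most abundant member Cela1, an elastase, was at 707 ± 43.2 CPM in p300_KO and 354 ± 171 CPM in Ep300_control. The delta, PP and epsilon cell list (camera adjusted p = 0.00788, and camera adjusted p = 0.349 with an estimated correlation; 3 higher adjusted over the list alone) and the ductal list (camera adjusted p = 0.0143, and camera adjusted p = 0.349 with an estimated correlation; 1 higher adjusted over the list alone) also passed upward. The cholesterol synthesis list (14 of 18 negative; camera adjusted p = 0.000515, and camera adjusted p = 0.411 with an estimated correlation) and the oxidative phosphorylation list (21 of 22 negative; camera adjusted p = 0.00523, and camera adjusted p = 0.676 with an estimated correlation) passed downward, with 0 called adjusted over either list alone. Without the library p300_KO 1, 3 lists passed in place of 5, with the lone p300_KO library assumed to vary like the other groups.

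Loss of CBP gave no called gene either. None of the hormone genes passed. Gcg was at 21055 ± 4768 CPM in CBP_KO and 28625 ± 10097 CPM in Crebbp_control (SD, n = 3 each; -0.40, SE 0.31), and Sst at 2129 ± 324 and 1672 ± 280 CPM (0.35, SE 0.23). Ppy was at 1456 ± 1451 and 1850 ± 1418 CPM (-0.29, SE 0.75), with 680, 559 and 3130 CPM in the libraries labelled CBP_KO 1, 2 and 3 and 2124, 3111 and 314 CPM in Crebbp_control 1, 2 and 3. Its value moved from 0.34 without Crebbp_control 2 to -1.28 without Crebbp_control 3, and was -2.06 (limma adjusted p = 0.0492) without the libraries labelled Crebbp_control 3 and CBP_KO 3. Ins1 was at 17880 ± 8798 and 15473 ± 2077 CPM (0.11, SE 0.39), and Ins2 at 67402 ± 25433 and 62411 ± 16570 CPM (0.07, SE 0.37). Chga, which encodes the granule protein chromogranin A, was at 10195 ± 787 and 14207 ± 1200 CPM (-0.48, SE 0.25), and the collagen gene Col3a1 at 34.5 ± 18.8 and 15.4 ± 5.66 CPM (1.06, SE 0.61). Limma called 0 genes higher and 0 lower, with 323 at an unadjusted p under 0.05, fewer than the 806 given by chance. Limma-trend and the fit of these groups alone also called 0. In alternatives chosen after seeing the data, limma called 1186 genes with weights per library (639 higher, 547 lower) and 68 without the libraries labelled Crebbp_control 3 and CBP_KO 3 (9 higher, 59 lower). The libraries did not overlap for 6.77% of genes, against 10% by chance. Without the library labelled Crebbp_control 3, limma called 2 genes.

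The libraries labelled Crebbp_control 3 and CBP_KO 3 each stood apart from the rest of their group. Aqp4, a gene chosen after its values were seen, was at 49.8, 52.4 and 1.41 CPM in the control libraries 1, 2 and 3, and at 2.22, 2.42 and 56.9 CPM in CBP_KO 1, 2 and 3. Every difference given here for CBP_KO takes the labels as they stand, although the authors' deposited fold changes lay closer to values with this pair on exchanged sides. Among the lists, limma called 0 members, and 8 lists passed camera with the preset correlation but none with an estimated one. All 14 interferon response genes were positive (camera adjusted p = 2.05e-11, and camera adjusted p = 0.192 with an estimated correlation). So were all 12 mesenchymal markers (camera adjusted p = 0.000132, and camera adjusted p = 0.406 with an estimated correlation) and 14 of 15 genes repressed in normal beta cells (camera adjusted p = 5.25e-05, and camera adjusted p = 0.297 with an estimated correlation). Schwann and glial markers also passed upward (camera adjusted p = 0.00982, and camera adjusted p = 0.192 with an estimated correlation). Adjusted over the list alone, 3 Schwann and glial markers were higher, and 0 members of the other lists named here were called. Beta cell identity genes passed downward (19 of 26 negative; camera adjusted p = 0.000132, and camera adjusted p = 0.192 with an estimated correlation). So did HNF1A and its islet targets (camera adjusted p = 0.000132, and camera adjusted p = 0.206 with an estimated correlation). Alpha cell markers (camera adjusted p = 0.00406, and camera adjusted p = 0.192 with an estimated correlation) and the unfolded protein response (camera adjusted p = 0.00334, and camera adjusted p = 0.418 with an estimated correlation) also passed downward.

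No gene was called for a difference between the changes of the single knockouts. Limma called 0 genes for the CBP change minus the p300 change, with 296 at an unadjusted p under 0.05, and limma-trend called 0. In simulated data this contrast recovered 19.4% of genes changed 2-fold and 90.9% of those changed 8-fold, so small differences would mostly be missed. The simulations held no library displaced from its group, so in the real data large differences may be missed as well. Compared directly, without controls, 514 genes were higher and 916 lower in CBP_KO than in p300_KO, a contrast that includes the difference between the lines.

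Triallelic islets were changed broadly, with less glucagon and pancreatic polypeptide RNA, more somatostatin RNA and far more immunoglobulin RNA. Glucagon RNA fell: Gcg was at 8663 ± 3530 CPM in Triallelic, 50617 ± 1865 CPM in Ep300_control and 28625 ± 10097 CPM in Crebbp_control (SD, n = 3 each; -2.16, SE 0.27, limma adjusted p = 0.000115). Ppy fell to 92.8 ± 45.1 CPM (-4.34, SE 0.63, limma adjusted p = 0.000312). The insulin genes fell too, Ins1 to 9859 ± 4410 CPM (-1.12, SE 0.34, limma adjusted p = 0.0239) and Ins2 to 43853 ± 23201 CPM (-1.07, SE 0.32, limma adjusted p = 0.0232). In contrast Sst, the somatostatin gene, rose to 4852 ± 1981 CPM (1.49, SE 0.21, limma adjusted p = 0.000254). Against Crebbp_control alone, Ins1 (-0.77, limma adjusted p = 0.175) and Ins2 (-0.63, limma adjusted p = 0.247) did not pass. Ucn3 (chromosome 13, 3940688 to 3945349), which encodes the mature beta cell peptide urocortin 3, fell to 89.1 ± 23.1 CPM from 420 ± 76.0 and 560 ± 90.7 CPM in the control groups (-2.47, SE 0.18, limma adjusted p = 3.54e-06).

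**Figure D2:**
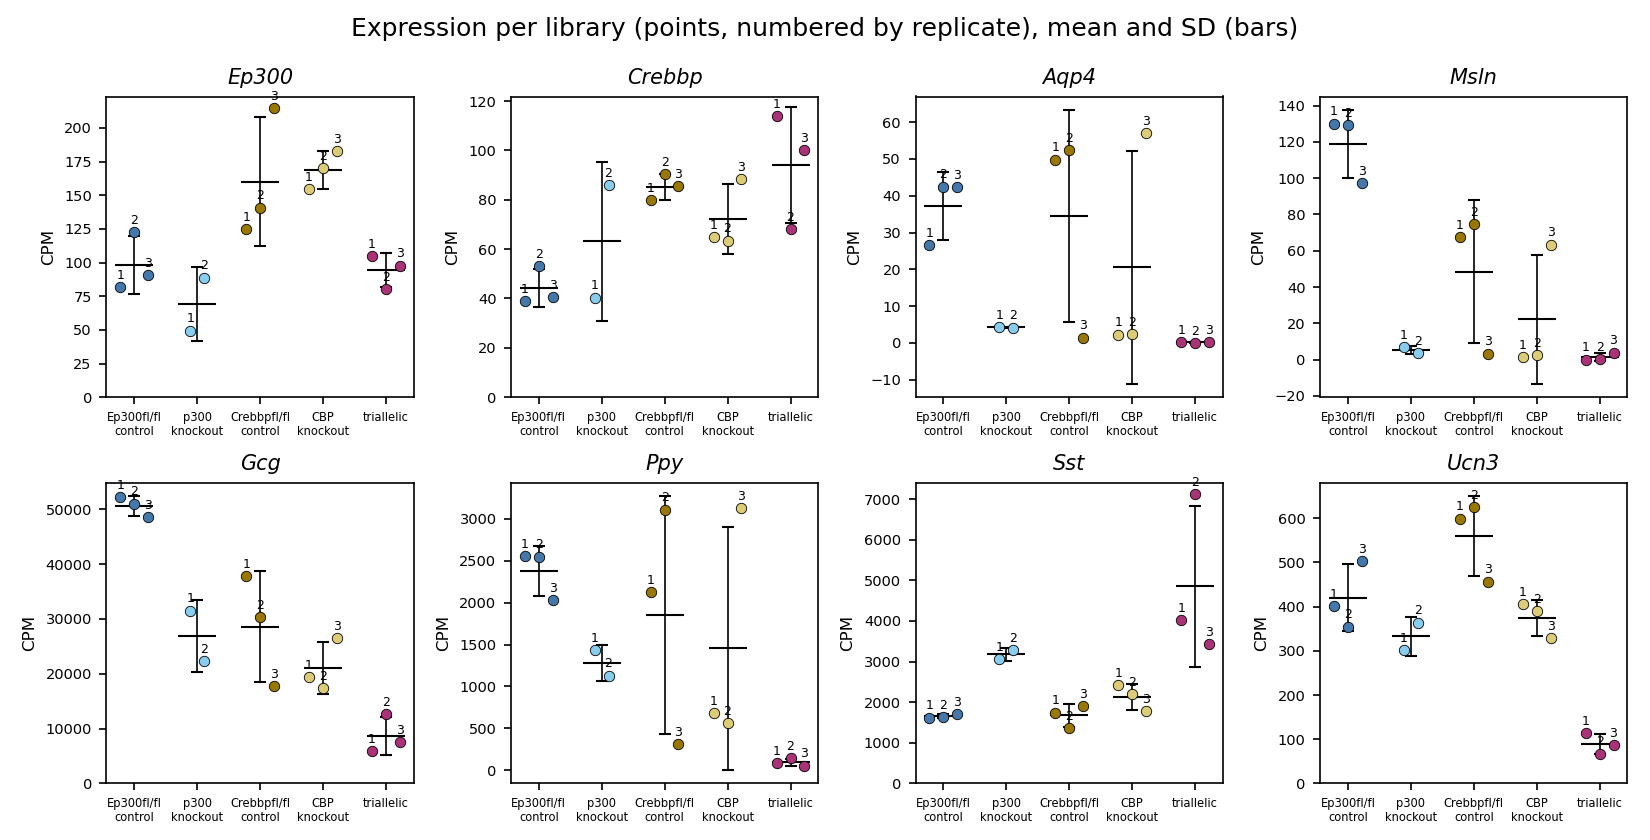
CPM per library of 8 genes (Ep300, Crebbp, Aqp4, Msln, Gcg, Ppy, Sst and Ucn3) in the 5 groups, with each point numbered by its replicate and bars for the group mean and SD. Gcg, Ppy and Ucn3 have their lowest group means in Triallelic islets (8663, 92.8 and 89.1 CPM), and Aqp4 in the libraries labelled Crebbp_control 3 (1.41 CPM) and CBP_KO 3 (56.9 CPM) lies far from the rest of their groups.

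Limma called 2817 genes higher and 2088 lower in Triallelic than in the mean of the control groups, which is 30.4% of those tested. The libraries did not overlap for 17.4% of genes, against 2.38% by chance. Against each control group separately, 1138 were higher and 845 lower than both, and 110 were called in opposite directions. Without the male library Triallelic 1 the count was 2764. Among called genes under the naming rule, with its minimum of abundance, the largest rises were those of the immunoglobulin constant regions Ighm (9.73, SE 0.67, limma adjusted p = 2.74e-06; 988 ± 599 CPM against 4.03 ± 1.33 and 0.297 ± 0.209 CPM) and Igkc (9.66, SE 0.55, limma adjusted p = 7.09e-07; 950 ± 639 against 2.23 ± 0.528 and 0.699 ± 0.711 CPM). Next under this rule were the cytochrome P450 gene Cyp1b1 (5.90; 126 ± 109 CPM), the haematopoietic myosin gene Myo1g (3.94) and Arhgap45 (3.94). Under the same rule, the largest falls were in Olfm4, which encodes the secreted glycoprotein olfactomedin 4 (-8.20; 0.180 ± 0.225 CPM against 45.3 ± 7.02 and 32.9 ± 19.5 CPM), and in Cdh7, at a total of 3 counts over the Triallelic libraries against 17.1 ± 3.39 and 13.2 ± 5.73 CPM in the controls. They also included the protease gene Tmprss4 (-6.83), Adora3 (-6.59; 0.311 ± 0.0588 CPM) and the sulfotransferase gene Sult1d1 (-5.62).

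Of the genes for beta cell identity and function, 17 of 26 fell and 1 rose (18 and 1 adjusted over the list alone; camera adjusted p = 1.07e-06, and camera adjusted p = 0.133 with an estimated correlation). Besides Ucn3, the taste-pathway cation channel gene Trpm5 (-2.47) and the granule-docking gene Sytl4 (-1.36) fell. The member that rose, named after its value was seen, was Mafa (1.47), at 17.1 ± 3.17 CPM in Ep300_control, 185 ± 63.7 CPM in Crebbp_control and 156 ± 44.3 CPM in Triallelic, which is -0.22 against Crebbp_control alone. Against Crebbp_control alone, 18 of these genes fell and 0 rose, and this list kept its call with an estimated correlation (camera adjusted p = 0.0259). Against Ep300_control alone, 13 fell and 4 rose, and the list did not keep its call (camera adjusted p = 0.477 with an estimated correlation). Of HNF1A and its islet targets, 11 of 13 fell and 0 rose, as they did adjusted over the list alone (camera adjusted p = 2.85e-06, and camera adjusted p = 0.206 with an estimated correlation). They included the phosphatase inhibitor gene Ppp1r1a (-2.53, SE 0.20, limma adjusted p = 5.97e-06; 47.9 ± 9.22 CPM against 219 ± 27.9 and 358 ± 119 CPM), the pyruvate kinase gene Pklr (-1.98) and the islet glucose-6-phosphatase gene G6pc2 (-1.21). Of the genes repressed in normal beta cells, 12 of 15 rose and 0 fell (14 rose adjusted over the list alone; camera adjusted p = 2.85e-06, and camera adjusted p = 0.237 with an estimated correlation). Among them were the lactate dehydrogenase gene Ldha (1.46), the monocarboxylate transporter gene Slc16a1 (1.41) and the thioesterase gene Acot7 (1.87). Against Ep300_control alone 9 of them rose. Some members of that list, such as Pdgfra, are also expressed by mesenchymal cells, whose markers rose as well.

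Of the alpha cell markers, 7 of 12 fell and 2 rose, as they did adjusted over the list alone (camera adjusted p = 0.00202, and camera adjusted p = 0.206 with an estimated correlation). Besides Gcg, the transthyretin gene Ttr (-2.61) and the amino acid transporter gene Slc7a2 (-0.68) fell. In this and the following lists of few called members, those outside the naming rule were named after their values were seen. The alpha cell markers that rose were Arx, an alpha cell transcription factor (0.59), and the secretin receptor gene Sctr (2.40). In the delta, PP and epsilon list, 3 of 7 rose and 1 fell, as they did adjusted over the list alone: Sst, its regulator Hhex (0.84) and Ghrl (2.24) rose, and Ppy fell (camera adjusted p = 0.480, with a median of 0.11 and a mean of -0.04). Granule and exocytosis genes fell in 8 of 20 and rose in 1, as they did adjusted over the list alone (camera adjusted p = 0.0116, and camera adjusted p = 0.237 with an estimated correlation). The granins Chga (-1.29) and Scg2 (-1.52) and Rab27a (-0.65), which docks granules, fell. Pcsk1n, which encodes a convertase inhibitor, rose by 1.87, but by 0.29 and below the threshold against Crebbp_control alone. Of the dedifferentiation and progenitor markers, 4 of 9 rose and 3 fell, as they did adjusted over the list alone (camera adjusted p = 0.515). The peptide hormone gene Cck (3.71), the progenitor transcription factor genes Sox9 (1.59) and Neurog3 (0.72) and the aldehyde dehydrogenase gene Aldh1a3 (1.47) rose, and Serpina7 (-2.15), Slc5a10 (-2.30) and Myt1 (-0.53) fell.

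Markers of other cell types moved unevenly. Immune markers rose in 4 of 15 and fell in 0, as they did adjusted over the list alone (camera adjusted p = 0.00197, and camera adjusted p = 0.445 with an estimated correlation). Cd19, the B cell coreceptor, was at 9.58 ± 3.83 CPM against 0.118 ± 0.146 and 0 CPM. The pan-leukocyte phosphatase gene Ptprc (2.94), the macrophage gene Cd68 (0.96) and the T cell receptor gene Cd3e (4.88) rose as well. Mesenchymal markers rose in 6 of 12 (8 adjusted over the list alone; camera adjusted p = 0.00103, and camera adjusted p = 0.445 with an estimated correlation). They included Pdgfra (3.07), Thy1 (1.81) and the pericyte gene Rgs5 (1.44). Against Crebbp_control alone, 11 of 12 mesenchymal and 12 of 15 immune markers rose. Against Ep300_control alone 3 rose of either list, and 2 mesenchymal markers and 1 immune marker fell. Ductal markers rose in 5 of 10 and fell in 1 (5 and 2 adjusted over the list alone; camera adjusted p = 0.107), with Cldn3 (2.25), the osteopontin gene Spp1 (2.12), Sox9, Cftr (2.06) and Epcam (0.78) up and Hnf1b (-0.62) down. Schwann and glial markers rose in 2 of 6, as they did adjusted over the list alone, S100b (1.78) and Sox10 (1.36; camera adjusted p = 0.333). Both stayed at low levels, with S100b at 0.742 to 1.24 CPM and Sox10 at 0.618 to 1.98 CPM in the Triallelic libraries. Sox10 reached 0.945 CPM in Crebbp_control 2, so its libraries overlapped. Endothelial markers rose in 2 of 12 and fell in 2, as they did adjusted over the list alone (camera adjusted p = 0.480), with Plvap and Pecam1 (0.67) up and Emcn (-0.54) and Esm1 (-0.47) down. Plvap was at 32.0 to 108.2 CPM in the Triallelic libraries and 38.9 to 63.3 CPM in Crebbp_control, so these groups overlapped. In Ep300_control it was at 18.4 to 27.4 CPM. The Esm1 libraries lay at 57.7 to 89.6 CPM in Triallelic, 66.9 to 83.1 CPM in Ep300_control and 120.5 to 153.8 CPM in Crebbp_control, so its fall was limited to the comparison with Crebbp_control. Of the acinar markers 1 of 18 fell, the transcription factor gene Bhlha15 (-1.20), and 0 were called adjusted over the list alone (camera adjusted p = 0.00244, and camera adjusted p = 0.534 with an estimated correlation). Acinar markers fell in 15 of 18 against Ep300_control alone and in 0 against Crebbp_control alone. The summed level of the 12 mesenchymal markers was 2328, 312 and 991 CPM in Triallelic 1, 2 and 3, and that of the 15 immune markers 1254, 300.1 and 839 CPM.

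**Figure D3:**
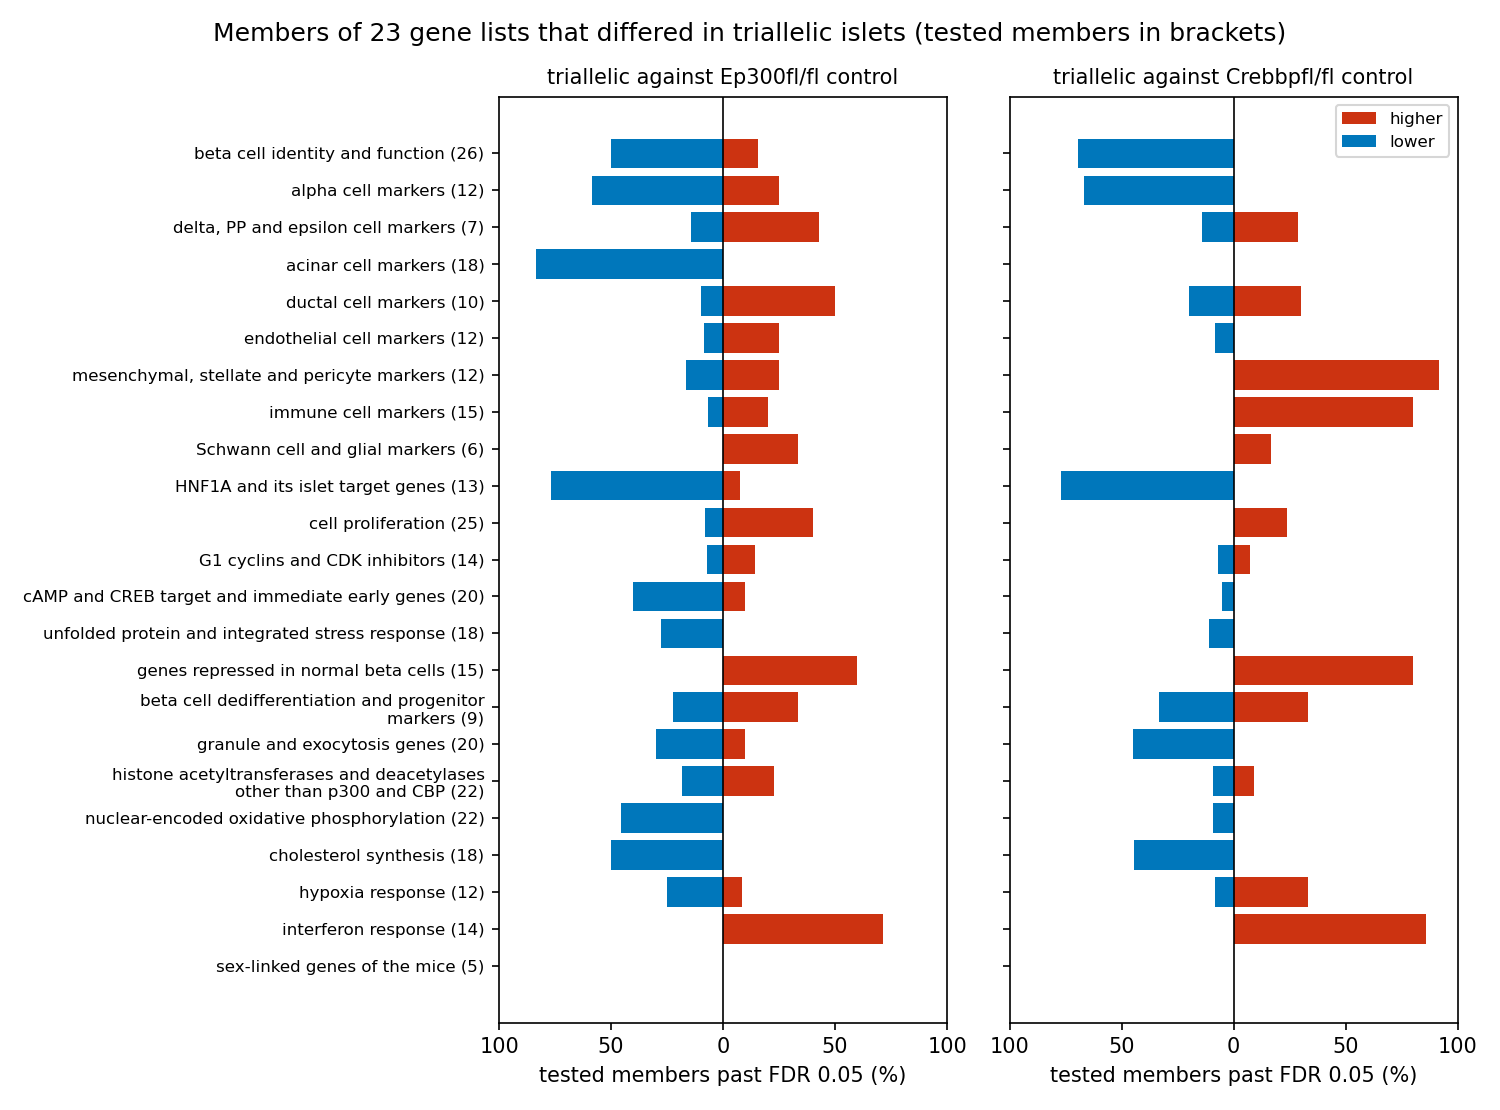
Bars give the percent of tested members of each of 23 gene lists that limma called higher (right of 0) or lower (left of 0) in Triallelic islets, against Ep300_control in the left panel and against Crebbp_control in the right panel, with the number of tested members in brackets. Beta cell genes were lower in both panels (13 and 18 of 26), whereas the acinar list had 15 of 18 lower against Ep300_control and 0 of 18 against Crebbp_control.

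Interferon response genes rose in 12 of 14 and fell in 0 (13 rose adjusted over the list alone; camera adjusted p = 5.06e-06, and camera adjusted p = 0.340 with an estimated correlation). Among them were the nucleic acid sensor gene Zbp1 (2.84), the ubiquitin-like modifier gene Isg15 (2.25) and Rtp4 (1.42). The summed level of the interferon list was 757, 389 and 553 CPM in Triallelic 1, 2 and 3, 218 to 351 CPM in the control libraries and 345 to 415 CPM in CBP_KO, so Triallelic 2 lay within the range of CBP_KO. It was highest in the Triallelic libraries richest in immune markers. Proliferation genes rose in 12 of 25 and fell in 1 (13 and 1 adjusted over the list alone; camera adjusted p = 0.000945, and camera adjusted p = 0.445 with an estimated correlation). Birc5, which encodes survivin (1.61), and the replication licensing gene Mcm5 (1.13) were among those that rose. The summed level of the proliferation list was 299 and 379 CPM in Triallelic 1 and 3, which were also richer in immune markers, but 207 CPM in Triallelic 2, within the 191 to 262 CPM of the control libraries. The 1 that fell was Tyms (-0.93), which was at 34.8 ± 3.42 CPM in Ep300_control, 7.37 ± 1.33 CPM in Crebbp_control and 8.37 ± 1.26 CPM in Triallelic. It was 0.19 higher against Crebbp_control alone. Of the G1 cyclins and CDK inhibitors 3 of 14 rose and 1 fell, as they did adjusted over the list alone (camera adjusted p = 0.578), with Cdk6 (1.69) and Ccnd3 (0.44) up and Ccnd2 (-0.40) down. Cdkn1b was called at 0.48 but lay at -0.00123 against Crebbp_control alone.

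Cholesterol synthesis genes fell in 10 of 18 and rose in 0 (12 fell adjusted over the list alone; camera adjusted p = 3.74e-05, and camera adjusted p = 0.237 with an estimated correlation). They included the rate-limiting reductase gene Hmgcr (-0.71) and the farnesyl diphosphate synthase gene Fdps (-1.50). Idi1 had the largest of these values (-2.16), but was at 58.3 ± 4.72 CPM in Ep300_control, 4.23 ± 1.56 CPM in Crebbp_control and 3.25 ± 1.16 CPM in Triallelic. Oxidative phosphorylation genes fell in 7 of 22 (9 adjusted over the list alone; camera adjusted p = 0.00103, and camera adjusted p = 0.445 with an estimated correlation). The complex I genes Ndufs2 (-0.69), Ndufs1 (-0.57) and Ndufs3 (-0.53) fell. The fall of Ndufs3 was limited to the comparison with Ep300_control, since it lay at 40.3 ± 3.11 CPM in Crebbp_control and 40.3 ± 5.72 CPM in Triallelic. Stress response genes fell in 5 of 18 (6 adjusted over the list alone; camera adjusted p = 0.00197, and camera adjusted p = 0.445 with an estimated correlation). The chaperone genes Hspa5 (-0.79) and Calr (-0.51), the neurotrophic factor gene Manf (-0.66), Atf4 (-0.52) and Pdia4 (-0.46) fell. Hypoxia response genes rose in 4 of 12 and fell in 2, as they did adjusted over the list alone (camera adjusted p = 0.930, with a median of -0.06 and a mean of 0.22). The glucose transporter gene Slc2a1 rose by 0.87, as did Car9 (1.60), Egln3 (1.23) and Pfkfb3 (1.12), and Bnip3 fell by 0.67, whereas Pgk1 (-1.42) was 0.33 higher against Crebbp_control alone.

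The cAMP and immediate early list had 1 member up and 2 down of 20, as adjusted over the list alone (camera adjusted p = 0.124): Ier2 (1.10), the coactivator gene Ppargc1a (-1.18) and Fosb (-2.19). Fosb was at 74.5 ± 2.05 CPM in Ep300_control, 2.54 ± 0.957 CPM in Crebbp_control and 3.16 ± 1.39 CPM in Triallelic, and so was 0.29 higher against Crebbp_control alone. Other histone acetyltransferases and deacetylases rose in 3 of 22 and fell in 3, as they did adjusted over the list alone (camera adjusted p = 0.578), with Hdac7 (0.89), Hdac5 (0.54) and the deacetylase gene Sirt1 (0.49) up and Kat2b (-0.40), Kat8 (-0.45) and Hdac6 (-0.63) down. Of the sex-linked genes 0 of 5 were called by limma, with or without adjustment over the list alone (camera adjusted p = 0.578), with Xist at -3.10 with the male library included and at 0.84 without Triallelic 1.

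Triallelic and p300_KO islets, which by their labels differ by 1 allele of Crebbp, differed in 2025 genes, 925 higher and 1100 lower in Triallelic by limma. This contrast includes the difference between the lines, because on the first principal component p300_KO lay with the Ep300 line and Triallelic with the Crebbp line. It also includes the male library Triallelic 1. The count therefore cannot be assigned to the Crebbp allele. Igkc (8.57) and Ighm (8.31) were again the largest rises under the naming rule, followed by Nrtn (4.94). Its largest falls were in Myoc, which encodes myocilin (-6.82; 54.7 ± 3.17 CPM in p300_KO and 0.473 ± 0.156 CPM in Triallelic), Olfm4 (-6.15; 8.50 ± 2.19 and 0.180 ± 0.225 CPM) and Hmcn2 (-5.29; 32.2 ± 2.28 and 0.803 ± 0.757 CPM). Of these, Myoc also separated the control groups (57.3 ± 1.08 CPM in Ep300_control and 0.475 ± 0.242 CPM in Crebbp_control), as did Hmcn2 (35.6 ± 3.17 and 0.492 ± 0.196 CPM) and Nrtn. Acinar markers fell in 16 of 18 (18 adjusted over the list alone; camera adjusted p = 3.75e-12, and camera adjusted p = 0.451 with an estimated correlation). The acinar list also separated the control groups, with 13 of 18 higher in Ep300_control, and fell in 0 of 18 in Triallelic against Crebbp_control alone. Beta cell genes fell in 9 of 26 and rose in 2 (11 and 2 adjusted over the list alone; camera adjusted p = 0.00165, and camera adjusted p = 0.451 with an estimated correlation). HNF1A and its targets fell in 7 of 13 (9 adjusted over the list alone; camera adjusted p = 0.000213, and camera adjusted p = 0.451 with an estimated correlation). Interferon response genes rose in 4 of 14 (9 adjusted over the list alone; camera adjusted p = 0.000541, and camera adjusted p = 0.642 with an estimated correlation). The libraries did not overlap for 37.6% of genes, against 20% by chance. The count was 686 without p300_KO 1, 945 without p300_KO 2 and 3372 without Triallelic 2. In fits without a p300_KO library the remaining one is assumed to vary like the other groups, which supply the spread.

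Of the 122 genes called in p300_KO in the 2-group fit, 32 higher and 90 lower, 119 had the same direction in Triallelic, where 107 were called. In CBP_KO, 107 had the same direction by the limma model and 0 were called. By plain means of log2 CPM it was 108, which 5 of the 20 ordered splits of the 6 Crebbp line libraries reached, so with the labels as they stand this count did not set CBP_KO apart from other groupings. Without the libraries labelled Crebbp_control 3 and CBP_KO 3, a pair doubted after its values were seen on these genes, limma called 5 genes higher and 31 lower in both single knockouts and 0 in opposite directions, where independent lists would share 0.00953 and 0.231. Against Crebbp_control, which shares no library with the p300 comparison, 20 of the genes that rose and 73 of those that fell in p300_KO were also called in that direction in Triallelic, where independent lists would share 3.58 and 8.51. Over all genes, log2 differences correlated with r = 0.228 between p300_KO and CBP_KO, where simulated unchanged groups gave -0.00126 on average. The correlation was 0.358 between p300_KO and Triallelic and 0.401 between CBP_KO and Triallelic. Simulated unchanged groups that share these controls gave 0.268 and 0.294 on average. The simulations held no library displaced from its group, so shared controls may contribute more in the real data. The covariances were 0.0437, 0.194 and 0.196, against simulated values of -0.000148, 0.0266 and 0.0269. With Triallelic set against the control group not used by the other comparison, r was 0.250 for p300_KO and 0.236 for CBP_KO. Correlations across genes treat genes that are not independent as if they were replicates, and no test was made on them.

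The authors' deposited tables list 761 genes for p300_KO (284 higher, 477 lower), 923 for CBP_KO (410 higher, 513 lower) and 5589 for Triallelic (3178 higher, 2411 lower). The single knockouts share 363 genes in the authors' deposited tables, 362 of them in the same direction, and 347 are in all 3 lists, 124 higher and 222 lower in each. Ppy has log2 fold changes of -1.08, -2.34 and -5.01 in the authors' deposited tables for p300_KO, CBP_KO and Triallelic, and Aqp4 values of -3.21, -4.69 and -8.12, where the limma model with the labels as they stand gave Aqp4 -1.03 for CBP_KO. In the authors' deposited table for p300_KO, Ep300 itself has a log2 fold change of -0.66 (adjusted p = 0.0415 in that table). In their table for Triallelic it has -0.58 (adjusted p = 0.0185 in that table). Genes of an HNF1 motif set were 2.34, 2.49 and 1.66 times as frequent as their expected number in the authors' deposited tables of enriched sets for p300_KO, CBP_KO and Triallelic, and genes for the regulation of hormone levels 2.97, 2.75 and 2.39 times. Another HNF1 motif set in those tables had ratios of 2.33 for CBP_KO and 1.49 for Triallelic. The limma model used here, with the 14 matched libraries, tested all listed genes for p300_KO and CBP_KO and 5492 of the 5589 for Triallelic. Of the listed genes tested, it called 0% for p300_KO and for CBP_KO and 69.0% for Triallelic, with the same direction for 100%, 88.7% and 98.8%. Over the genes of the authors' CBP list, log2 ratios of mean CPM differed from the deposited log2 fold changes by a median of 0.586 with the labels as they stand (r = 0.812 across genes). With Crebbp_control 3 and CBP_KO 3 on exchanged sides the median was 0.0621 (r = 0.996), the lowest of the 20 ordered splits, and without this pair it was 0.0902. For the authors' p300 list it was 0.0781. The authors' lists come from the same series and are not independent evidence.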

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

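The tests of the difference between the single knockouts were planned, whereas the tests on the libraries labelled Crebbp_control 3 and CBP_KO 3 were chosen only after the result was seen.

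For 6 gene lists the change in CBP_KO differed from the change in p300_KO by camera (two-sided, preset correlation, adjusted over 23 lists), although limma called 0 single genes for this difference, with 296 at an unadjusted p under 0.05. The acinar list was lower in the CBP change than in the p300 change (17 of 18 genes negative, median -1.21, camera adjusted p = 4.01e-07), as was the beta cell identity list (18 of 26 negative, median -0.20, camera adjusted p = 0.0338). The interferon response list was higher (14 of 14 positive, median 0.53, camera adjusted p = 0.000209), as were cholesterol synthesis (15 of 18 positive, median 0.28, camera adjusted p = 0.000799), mesenchymal, stellate and pericyte markers (12 of 12 positive, median 0.72, camera adjusted p = 0.0171) and genes repressed in normal beta cells (12 of 15 positive, median 0.43, camera adjusted p = 0.0338). None of these calls held with an estimated correlation: camera adjusted p = 0.426 with an estimated correlation for the beta cell, acinar, cholesterol and interferon lists, and camera adjusted p = 0.688 with an estimated correlation for the mesenchymal and repressed lists. The number of lists passing was 3 without Crebbp_control 2, 3 without CBP_KO 2 and 8 without the library labelled Crebbp_control 3. The cholesterol list summed to 1835, 1825 and 1578 CPM in Crebbp_control 1, 2 and 3 and to 1508, 1626 and 2394 CPM in CBP_KO 1, 2 and 3. For that list only the library labelled CBP_KO 3 lay above the controls. The interferon list, by contrast, summed to 345 to 415 CPM in CBP_KO and 218 to 328 CPM in Crebbp_control.

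Each of these differences uses libraries that stood out within their groups. On a scale over the 122 genes of the 2-group p300 fit, with the other Crebbp_control libraries at 0 and the other CBP_KO libraries at 1, the library labelled Crebbp_control 3 lay at 1.09 and the library labelled CBP_KO 3 at 0.0628, where libraries of a reference group differed by up to 0.0585. Incomplete deletion in the library labelled CBP_KO 3 cannot be the whole cause, because Crebbp_control 3, at 1.09, was displaced as well. A candidate explanation is an exchange of the labels of this pair. The level of Crebbp, the deleted gene, goes with an exchange in CBP_KO 3 (88.4 CPM, above the midpoint of 74.6 CPM, on the control side) and against it in the library labelled Crebbp_control 3 (85.4 CPM, also on the control side), and whole-gene levels check the deletion only weakly.

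The authors' deposited fold changes for CBP_KO did not follow the labels of this pair. Over the genes of the authors' CBP list, log2 ratios of mean CPM lay a median of 0.0621 from the deposited values with the pair on exchanged sides, the closest of the 20 ordered splits of the 6 libraries, 0.0902 without the pair and 0.586 with the labels as they stand. Those genes were picked by the authors under their own grouping, so this bears on how their list was made and not on which genotype each animal had. Whether the labels or the authors' grouping is right cannot be told apart here, since Crebbp does not decide it, and a biological difference between animals was not tested.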

How the results depend on the processing

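The weights per library, limma-trend and the fit without the libraries labelled Crebbp_control 3 and CBP_KO 3 were chosen only after the result was seen; the other alternatives were planned. Direction and side of the threshold held in all alternatives for 45 of 77 genes named for Triallelic, 6 of 6 for the control lines, 5 of 6 for Triallelic against p300_KO, 11 of 41 for p300_KO and 3 of 28 for CBP_KO, and the sign changed in at least 1 alternative for 5, 0, 0, 17 and 22. For p300_KO, limma called 122 genes in the fit of its groups alone, 80 without the doubtful pair of libraries and 7 with weights per library, against 0. For CBP_KO it called 68 without that pair and 1186 with weights, against 0. Leaving out single libraries gave 0 to 2 genes for CBP_KO (2 without Crebbp_control 3) and 0 for p300_KO, where a lone remaining library is assumed to vary like the other groups. The Triallelic count of 4905 was 2979 with the strict filter (5 CPM in 3 libraries), which tests fewer genes, and 2764 (without Triallelic 1) to 5308 when single libraries were left out. The count between control lines, 2841, was 7686 with weights and 1307 (without Ep300_control 1) to 2123 with single libraries left out, including 1663 and 1698 without Ep300_control 2 and 3 and 1473 and 1623 without Crebbp_control 2 and 3. Triallelic against p300_KO, 2025, was 1277 with the strict filter and 686 (without p300_KO 1), 945 (without p300_KO 2) and up to 3372 (without Triallelic 2) otherwise. The difference between the single knockouts, 0, was 1430 when p300_KO and CBP_KO were compared without controls, a contrast that contains the line. Fry passed 16 of 23 lists for Triallelic, 9 between the control lines and 6 for Triallelic against p300_KO, where camera with the preset correlation passed 13, 8 and 9. With an estimated correlation 0 lists passed camera in all 6 contrasts, and by fry 0 passed for p300_KO, CBP_KO and their difference, against 5, 8 and 6 with the preset correlation. With single libraries left out these numbers ranged from 3 (without p300_KO 1) to 7 for p300_KO and from 3 (without Crebbp_control 2, or CBP_KO 2) to 8 for the difference. Without the doubtful pair, r between p300_KO and CBP_KO was 0.431, against 0.228. Against the control group not shared, r between CBP_KO and Triallelic was 0.236, against 0.401. The share of tested genes in the authors' deposited tables called here was 10.1% (without the pair) and 14.6% (fit of the groups alone) for p300_KO and 7.26% (without the pair) for CBP_KO, against 0%. Against Crebbp_control alone, the Triallelic values of Tyms (0.19), Fosb (0.29), Pgk1 (0.33) and Cdkn1b (-0.00123) reversed sign, each being set by the level in the Ep300 line. Xist went from -5.80 without Triallelic 2 to 0.84 without the male library Triallelic 1. For the other changes the cause was not tested. DESeq2 alternatives were not run. No paired analysis was possible because replicates were numbered in accession order only. At 13037284 to 46586260 counts per library, depth limits genes below about 1 CPM, such as Cck.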

Other observations

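All tests in this part were chosen only after the result was seen, except the test of GC content and gene length and the counts of other splits of the samples, which were planned.

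Several regulators outside the naming rule changed in Triallelic islets against either control group alone, and were picked here after their values were seen. Rest, a repressor of neuronal genes that is normally silent in endocrine cells, rose (1.37 against Crebbp_control and 2.61 against Ep300_control, limma adjusted p = 0.0307 and 0.00169). Hnf4a, a nuclear receptor gene that acts with HNF1A, fell (-0.88 and -0.90, limma adjusted p = 0.00722 and 0.00371), and Vil1, which encodes the microvillus protein villin, fell further (-3.65 and -3.82, limma adjusted p = 0.00263 and 0.00104). Hnf1a itself was not called against Crebbp_control (-0.15). Beta cell transcription factors split by control group: Nkx6-1 was at -0.79 against Crebbp_control and 1.17 against Ep300_control, and Neurod1 at -0.85 and 0.49, because both already differed between the control lines (-1.96 and -1.34).

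The difference between control lines (2841 genes) did not come from GC content or gene length as a whole, since limma-trend called 3483 genes after each library's trends on both were removed and 2940 before, 2610 of them in both sets. Among these, 161 genes more than 8-fold higher in Ep300_control at 10 CPM or more had a median coefficient of variation of 7.42% over the 5 libraries of the Ep300 line, against 15.5% for uncalled genes of the same level. They summed to 12748 ± 1166 CPM there and 851 CPM in the Crebbp line. Called genes tend to vary less than uncalled ones by selection alone, so the lower variation cannot decide on a cause. A fixed share of RNA or reads from 1 other source in these 5 libraries may account for the 161 genes, along with low Ddx3y counts in libraries with female Xist levels, but not for the 1334 genes lower in that line. Across genes p300_KO minus CBP_KO followed Ep300_control minus Crebbp_control with r = 0.887, and 99.3% of the 2841 genes kept their sign. Triallelic mice carry both floxed Ep300 alleles too, yet their libraries lay with the Crebbp line on the first principal component. Their scores were 33.8 to 49.8, against -91.4 to -75.0 in the Ep300 line. The difference on that axis therefore did not follow the floxed Ep300 alleles themselves. Other features of the line, cohort and batch cannot be told apart here, because they coincide.

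Triallelic islets held more B cell, other immune and mesenchymal RNA than Crebbp_control. A lower share of endocrine cells alone would raise every other cell type alike, whereas the acinar median was 0.0842 and the endothelial median 0.118, against an immune median of 1.64 with a quartile deviation of 0.72. The male library Triallelic 1 alone does not account for it, since the immune median was 1.34 without that library. All 3 B cell genes examined (Cd19, Ighm and Igkc) lay above every control library in each Triallelic library. However, Ighm and Igkc had been named by a rule that requires non-overlapping libraries, and Cd19 as the immune marker with the smallest adjusted p. Their separation was therefore set by how they were picked and is no test of a source. Lymphocytes or lymphoid tissue in the preparation remain a possible source. Whether such cells infiltrated the islets or were carried along in isolation was not tested.

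A further hypothesis was a graded effect of the number of alleles lost. On a scale with the mean of Ep300_control at 0 and the mean of p300_KO at 1 over the 122 genes, the Triallelic libraries lay at 1.72 to 1.89 and the p300_KO libraries at 0.960 to 1.04, and 105 of the genes lay further from control in Triallelic. This is consistent with a graded effect, but the genes were chosen in p300_KO and the line of the Triallelic mice may contribute. For CBP_KO, 108 of the 122 genes had the sign seen in p300_KO by plain means of log2 CPM (107 by the limma model), but 5 of the 20 ordered splits of the 6 libraries gave as many, the highest other giving 118, so with all 6 libraries as labelled this count did not tell a shared effect from other groupings. Without the libraries labelled Crebbp_control 3 and CBP_KO 3, 5 genes were called higher and 31 lower in both single knockouts and 0 in opposite directions, where independent lists would share 0.00953 and 0.231. That pair was left out because of its place on genes changed in p300_KO, so this overlap is not independent evidence, and a shared effect stays open.

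The 6 libraries of the CBP comparison make only 10 splits, too few for a share under 0.05, and a real count of 0 genes by limma (323 at an unadjusted p under 0.05, 0 by limma-trend) is reached by any split, so the count of splits says nothing here. The highest other gave 247. That split joins the library labelled CBP_KO 3 with Crebbp_control 1 and 2, which points to a structure of the samples other than the labels. The libraries of the control lines also make only 10 splits, with 1 reaching the real count of 2841 and 0 genes in the highest other. For Triallelic against both control groups, 1 of 100 drawn splits reached 4905, the real one, with 2674 in the highest other. Drawn splits could mix the control lines within a group, which raises the spread and lowers their counts. The real count was thus the highest of those drawn, but chance is not excluded.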
